A study of Arabidopsis thaliana with 6 samples.

How the data were processed

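Aerial parts of Arabidopsis plants 4 weeks old were profiled on Affymetrix arrays, 3 from wild type and 3 from albino msh1 mutants. Per the labels, the plants grew on MS medium with 1.5% sucrose in 12 h light and 12 h dark at 24 °C. Total RNA of each plant was purified with TRIzol and RNeasy and labelled as biotinylated cRNA. Samples were grouped as the labels name them, and the labels give no batch.

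The deposited values are on the log2 scale, 1 value per probe set and array. The authors made them with RMA (background correction, normalization between arrays and summary per probe set) in the affy package. Versions, settings and the genome build are not given in the sources used here. The values were used as deposited, without rescaling or filtering, in the main comparison. Apart from 64 array controls, 22746 probe sets were tested. The depth of an array is not a count, and the number of arrays limits the precision; the median SE of a difference was 0.118 on the log2 scale.

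Probe sets were named from the array annotation and the TAIR10.1 gene table, which was used for names and neighbouring genes only. A single gene was given for 13513 probe sets, several for 503, and 8730 were unnamed here. Of the single-gene probe sets, 13436 were matched by gene number, 48 by locus, 23 by the symbol of a mitochondrial gene, and 6 kept the older name. Where a gene had several probe sets, lists used the one with the highest mean over all arrays, giving 13355 genes. In the 147 genes with more than 1 probe set, 0 had opposite calls, 6 had all called the same way and 15 had some called and some not. Of the called probe sets 1302 had a single gene and 1245 did not.

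Each probe set was tested with lmFit and eBayes of limma (limma 3.58.1 in R 4.3.3, two-sided), as msh1 albino minus wild type, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. At an unadjusted p under 0.05, 5835 probe sets passed. A 2-fold difference is 1 on the log2 scale. Intervals are at 95%. Comparisons of single values per array used two-sided exact permutation tests, whose smallest p is 0.1 with 3 against 3 arrays.

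Before the data were examined, 34 gene lists, the named-gene rule and most alternatives were fixed. Of 420 loci listed by name, 69 were measured, meaning that the annotation paired a single-gene probe set with them. The other loci may still lie among the 8730 unnamed probe sets or those given several genes. Counts of list members refer to measured members. Lists were tested with camera (preset correlation 0.01) where at least 3 members were measured, which gave 16 lists, adjusted together. With the preset correlation 10 were called, 4 up and 6 down; with an estimated correlation 0 were called (smallest adjusted p = 0.248), and fry called 12. fry tests whether genes of a list move one way on balance and compares them with no other genes. Some rules were adapted to the annotation. The plastid list took protein-coding genes of the plastid chromosome, the mitochondrial list was matched by symbol or synonym, rules on gene descriptions were read as rules on symbols and synonyms, and 3 members were dropped because their name belonged to another locus, 1 of the chlorophyll and haem list and 2 of the DNA damage list. A further 16 lists (photosystem, NADH dehydrogenase-like, ATP synthase, ribosomal and polymerase genes of the plastid; respiratory and cytochrome c maturation genes of the mitochondrion; chloroplast biogenesis, tricarboxylic acid cycle, branched-chain amino acid breakdown, autophagy, iron, stomatal lineage, tau class glutathione transferases, UGT73 to UGT76, and expansins with xyloglucan enzymes) were written after the annotation, array summaries and control values had been seen and before any difference between groups was computed. Of these camera called 8, 0 with an estimated correlation (smallest adjusted p = 0.339), and fry called 3. Gene families of at least 5 symbols with a shared stem were tested as well, 43 in all, of which camera called 1 and 0 with an estimated correlation.

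The named-gene rule took MSH1, the 10 genes with the highest and the 10 with the lowest difference among single-gene probe sets that passed with no overlap between groups, and for each list up to 4 passing members or, where none passed, the 2 with the largest difference. Genes named outside it are said to be so. MSH1 was not analysed here because no probe set was paired with it in the annotation used.

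Alternatives were alignment on the 75th percentile or on the reference genes, cyclic loess, quantile normalization applied again, filters at the 25th and 50th percentile of the mean, an intensity trend with a robust prior, array weights, replicate number as a block, dropping probe sets that share sequence with other transcripts, an adjusted p of 0.01, 1 probe set per gene, the mean of all probe sets per gene, an estimated correlation, fry, and leaving out each array. Alignment on the spiked hybridization controls was added after the data were seen.

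The fit was tested on simulated data with the same design in 20 simulations. In each, 200 of 22746 probe sets were changed, shared equally between 2-fold and 4-fold differences. With variances drawn from the fitted prior, 83.3% of 2-fold and 98.1% of 4-fold differences were recovered and 4.50% of calls were false; a planted list was called in 20 of 20 and other lists in 1 of 300 tests. With the moderated variance of each probe set, 94.5% and 99.5% were recovered, 6.03% of calls were false and other lists were called in 7 of 300 tests. The shares recovered hold for 200 changed probe sets, against 2547 called in the data, and recovery with that many changed was not simulated. Simulated probe sets were drawn independently of each other, so the list results hold for uncorrelated genes only. They do not show how often camera with the preset correlation calls lists of correlated genes.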

Results

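The data are transcript levels of 6 Affymetrix arrays, 3 from wild-type Arabidopsis and 3 from albino tissue of msh1 mutants, each array from a separate biological replicate. MSH1 is a nuclear gene for a MutS homolog that acts in mitochondria and plastids, where it limits recombination of the organelle genomes. The aerial part of plants 4 weeks old was sampled. Every array gave values for 22746 tested probe sets and 64 array controls. The 75th percentile of log2 values lay between 7.75 and 7.94 in each array, and the number of arrays limits the precision. Arrays of the same group correlated at r = 0.989 to 0.995 across probe sets and arrays of different groups at r = 0.969 to 0.985. Probe sets are not independent replicates. The transcript of MSH1 itself was not analysed here.

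The comparison asks which transcripts differ between albino msh1 tissue and wild-type tissue. Every msh1 array came from albino tissue, so effects of the genotype and of the albino state cannot be told apart. Transcripts of plastid genes for photosystem II and for the large subunit of RuBisCO were among the named transcripts that fell most in the albino tissue. As a group, 29 plastid genes for photosystems, cytochrome b6f and RuBisCO had a median of -0.97. The nuclear lists for light harvesting and the Calvin cycle, of 3 measured genes each, had medians of -0.70 and -0.77. By camera with an estimated correlation the adjusted p was 0.339 for the plastid group and 0.248 for each nuclear list. Mitochondrion-encoded transcripts and nuclear transcripts of the mitochondrial stress list rose as groups by camera with a preset correlation (adjusted p = 0.248 for each with an estimated correlation). psbA, for the D1 protein of photosystem II, fell by 3.00 ± 0.21 on the log2 scale (SE, 3 arrays per group), which is 7.99-fold lower. AT1G30700, for a berberine bridge enzyme-like protein, rose by 3.32 ± 0.28, from a mean of 4.20 to 7.52. Background was not measured here, so a difference against a low mean such as 4.20 is a lower bound if that level is background. Of the probe sets tested, 2547 (11.2%) passed an adjusted p of 0.05, 854 of them higher and 1693 lower in the albino tissue. At least 2-fold differences were found among these for 363 higher and 243 lower probe sets. In 6799 probe sets (29.9%) the 3 arrays of one group lay beyond all 3 of the other, against 10% by chance. The split between higher and lower calls depended on scaling: 66.5% of calls were lower as deposited, 32.2% (1717 higher and 814 lower) with the arrays aligned on reference genes, 45.7% on the 75th percentile, 45.4% after cyclic loess, 52.2% after quantile normalization and 49.6% on spiked controls. Alignment on the reference genes moved the median difference of all probe sets from -0.04 to 0.11. Alignment on the spiked controls moved that median to -0.06 and left 1153 calls, so its share does not reflect a shift towards higher values. Leaving out any one array gave fewer calls than the 2547 with all arrays, and a test on fewer arrays also has less power. Higher and lower calls were 589 and 1201 without wild-type replicate 1, 298 and 553 without replicate 2, and 441 and 814 without replicate 3. They were 687 and 1109 without msh1 albino replicate 1, 685 and 1424 without replicate 2, and 749 and 1042 without replicate 3.

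By their RMA values, and with ranks that low wild-type levels leave uncertain, the 10 genes with the highest differences were AT1G30700, AT5G39580 (3.11 ± 0.42), AT1G65500 (3.07 ± 0.28), AT4G12490 (3.02 ± 0.21), AT4G12500 (2.94 ± 0.21), AT1G26380 (2.80 ± 0.18), OSM34 (2.74 ± 0.36), AT4G22470 (2.71 ± 0.35), PDF1.4 (2.64 ± 0.49) and MSRB9 (2.63 ± 0.24), each as log2 ± SE. AT5G39580 codes for a class III peroxidase, AT4G12490 and AT4G12500 for proline-rich proteins of the lipid-transfer family, and AT1G26380 for a second berberine bridge enzyme-like protein. OSM34 is an osmotin-like protein, PDF1.4 a defensin-like protein and MSRB9 a methionine sulfoxide reductase. Adjusted p-values of these genes ran from 0.000870 for AT1G26380 to 0.0150 for PDF1.4. The call of PDF1.4 was lost without wild-type replicate 2 (adjusted p = 0.0512, the highest of its alternatives).

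The 10 genes with the lowest differences were 7 plastid-encoded genes and the loci AT2G07777, AT3G28270 and AT1G22480. Both rankings cover single-gene probe sets only, and 1245 of the 2547 called probe sets had no single gene here and could not enter. AT2G07777 went from 7.18 ± 0.21 in wild type to 3.88 ± 0.22 in albino tissue (mean log2 value ± SD, n = 3 arrays), with a limma adjusted p of 0.000196; whether the albino level stands above background was not settled, so no fold is given. The locus lies on chromosome 2, which carries a nuclear copy of mitochondrial DNA, and which copy its probe set reads was not settled here. AT3G28270 fell by 2.34 ± 0.23. AT1G22480 fell by 2.65 ± 0.52, and its call was lost without wild-type replicate 1 (adjusted p = 0.0566), wild-type replicate 2 (0.0822) or msh1 albino replicate 3 (0.0519) and with an intensity trend in the variance prior (0.0568).

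**Figure D1:**
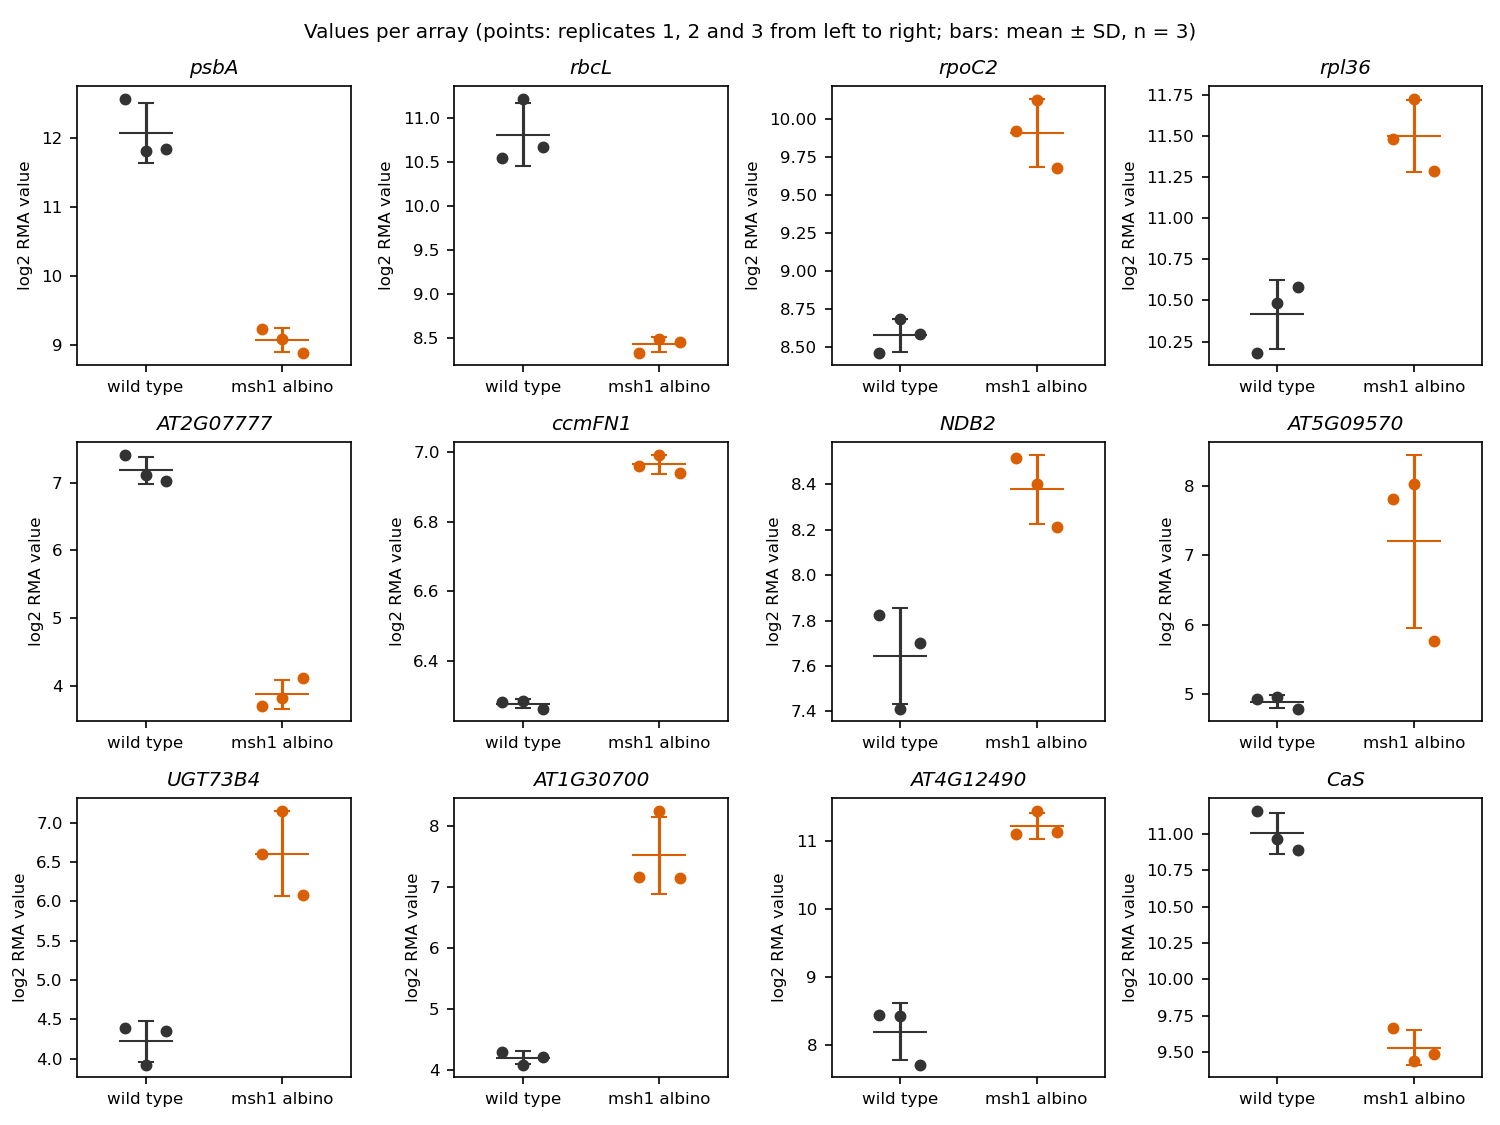
Log2 RMA values per array for 12 of the named genes, wild type in black and msh1 albino in orange, with 1 point per replicate and bars at the mean ± SD (n = 3). In AT2G07777 the wild-type mean is 7.18 and the msh1 albino mean 3.88. In AT5G09570 msh1 albino replicate 3 lies at 5.76, below the other albino replicates at 7.81 and 8.03.

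Of 69 measured plastid-encoded genes 21 fell and 6 rose, and adjusted over the list alone 28 fell and 8 rose. Without wild-type replicate 2 or without wild-type replicate 3, 17 fell and 3 rose, the 3 being rpoC2, rpl36 and ycf3 in both cases; 4 rose without msh1 albino replicate 1 or 2. Among those that passed over all probe sets, 18 were at least 2-fold lower and 4 at least 2-fold higher. The list as a whole fell relative to other genes, with a median of -0.35 (camera adjusted p = 1.93e-04; adjusted p = 0.376 with an estimated correlation). Besides psbA, the photosystem II genes psbB (-2.83 ± 0.38), psbC (-2.72 ± 0.26), psbH (-2.56 ± 0.19), psbD (-2.30 ± 0.25) and psbZ (-2.05 ± 0.28) fell, and rbcL, the large subunit of RuBisCO, fell by 2.38 ± 0.17. As a group, the 29 genes for photosystems, cytochrome b6f and RuBisCO fell by a median of 0.97, with 15 lower and 1 higher (adjusted p = 3.56e-10; adjusted p = 0.339 with an estimated correlation). The one higher was ycf3, a photosystem I assembly factor (1.13 ± 0.11), named after its values were seen. In the 10 genes of the NADH dehydrogenase-like complex ndhJ (-1.96 ± 0.16) and ndhK (-1.85 ± 0.19) fell and the group did not pass (median -0.31, adjusted p = 0.0762). With 1 array left out its median ran from -0.46 to -0.19, and 4 genes fell without wild-type replicate 1 and 3 without msh1 albino replicate 2. That group passed in 7 of 20 alternatives: without wild-type replicate 1 (adjusted p = 0.00112) or msh1 albino replicate 2 (0.0265), with the 75th percentile (0.0162), the reference genes (0.00791) or the spiked controls (0.00280) aligned, with array weights (0.0406) and with the replicate block (0.0470). Wild-type replicate 1 lay more than 1.5 on the log2 scale below the mean of the other wild-type arrays in 4 plastid genes, accD, ycf4, ndhH and psaA, of which psaA had a difference of -1.52 ± 0.78 and did not pass; ycf4, ndhH and psaA were named after their values were seen.

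Among plastid genes for gene expression rpoC2, a subunit of the plastid-encoded RNA polymerase, rose by 1.33 ± 0.13, and the ribosomal protein gene rpl36 rose by 1.08 ± 0.15. The 6 genes for the polymerase, accD and clpP rose as a group by camera with a median of 0.51 (adjusted p = 0.0118). That call was lost with an estimated correlation (adjusted p = 0.339) and by fry (adjusted p = 0.0633). In this group rpoC2 and rpoA were higher and accD, a subunit of acetyl-CoA carboxylase, was lower (-1.58 ± 0.39). The calls of rpoA and accD were both lost without wild-type replicate 2 (adjusted p = 0.171 and 0.131), wild-type replicate 3 (0.139 and 0.126), msh1 albino replicate 1 (0.131 and 0.101) and msh1 albino replicate 2 (0.102 and 0.0692), and accD also without msh1 albino replicate 3 (0.0949). In the 15 ribosomal protein genes 3 rose and 1 fell, with 1 higher and 0 lower without wild-type replicate 2 or 3 and 2 higher without wild-type replicate 1, msh1 albino replicate 1 or msh1 albino replicate 2 (2 lower without msh1 albino replicate 2) and 5 higher without msh1 albino replicate 3. The group did not pass (median 0.05, adjusted p = 0.118), except without msh1 albino replicate 3 (adjusted p = 0.00268), after cyclic loess (0.0499) or quantile normalization again (0.0250), and above the 50th percentile of the mean (0.0404). Of 6 ATP synthase genes 1 fell (0 by limma without wild-type replicate 3 and 3 without wild-type replicate 1), and camera called the list lower relative to other genes (median -0.42, adjusted p = 0.0431; adjusted p = 0.522 with an estimated correlation and 0.145 by fry). That call was lost in 10 of 20 alternatives, among them without wild-type replicate 2 (adjusted p = 0.107), wild-type replicate 3 (0.0846), msh1 albino replicate 1 (0.0785) and msh1 albino replicate 3 (0.0908). Within each array the mean of the polymerase, ribosomal, accD and clpP genes minus that of the photosynthesis genes was -0.42 ± 0.20 in wild type and 0.86 ± 0.13 in albino tissue (SD, n = 3), a difference of 1.28 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow).

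**Figure D2:**
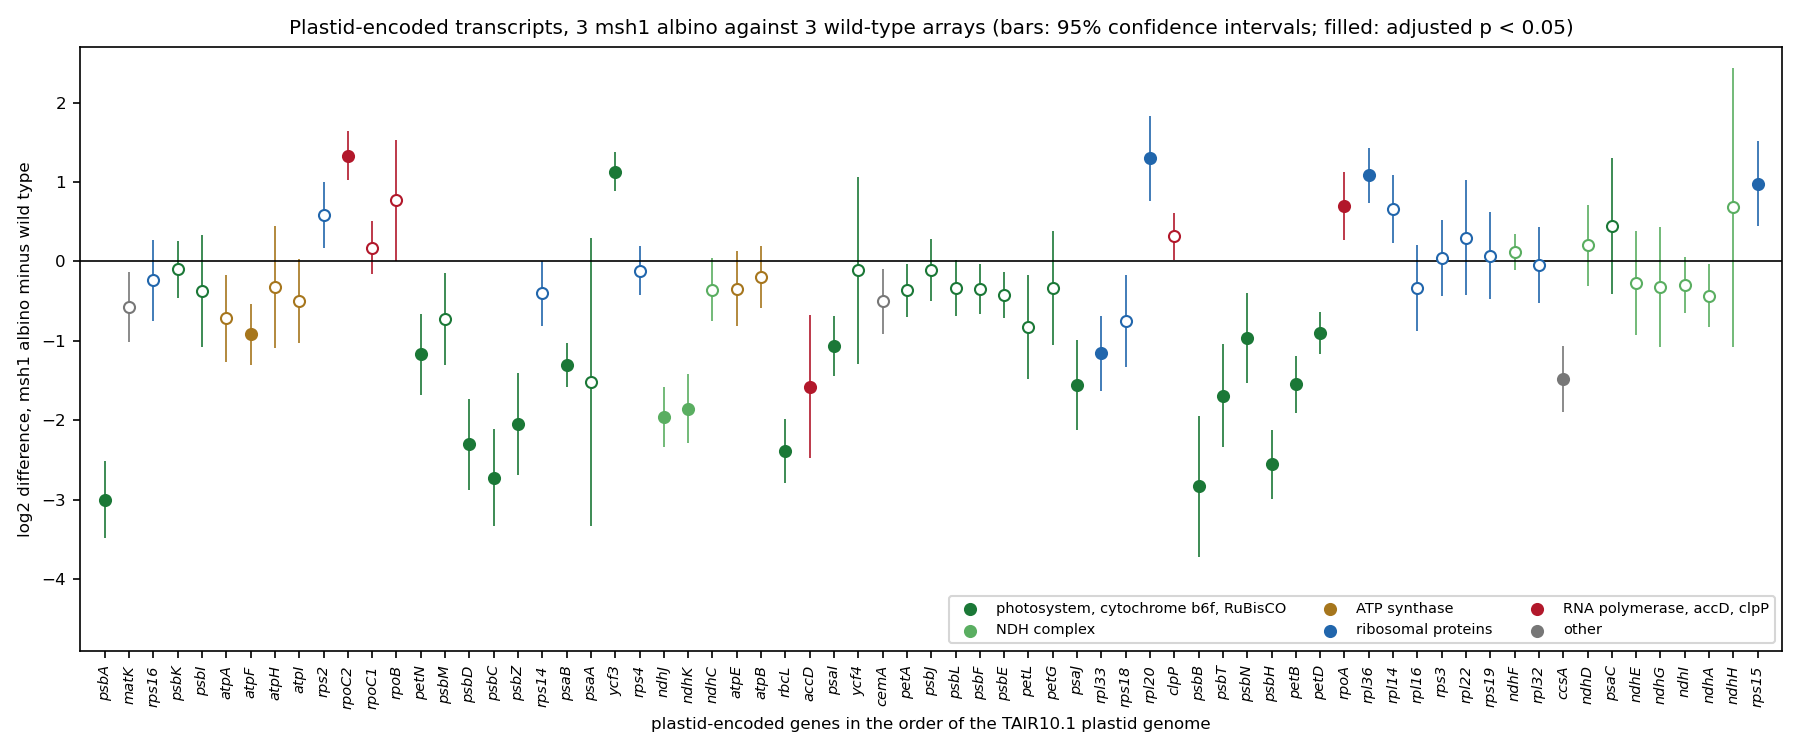
Log2 difference, msh1 albino minus wild type, of 69 plastid-encoded genes in genome order, with 95% confidence intervals and filled points at an adjusted p under 0.05. Colours mark gene classes; psbC lies at -2.72 and rpoC2 at 1.33.

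Nuclear genes for photosynthesis, in the part of each list that was measured, fell as groups by camera with the preset correlation, except photorespiration. Measured were 3 of 21 listed genes for light harvesting, 5 of 31 for the photosystems and 3 of 19 for the Calvin cycle. For chlorophyll and haem 7 of 21 were measured and for photorespiration 3 of 12. In the light-harvesting list LHCB4.2 (-1.08 ± 0.15) and LHCB4.1 (-0.70 ± 0.11), minor antenna proteins of photosystem II, fell, and 3 of 3 members fell adjusted over the list alone (median -0.70, adjusted p = 0.00353; adjusted p = 0.248 with an estimated correlation). In the photosystem list 3 of 5 members fell, and 5 adjusted over the list alone (median -0.77, adjusted p = 6.40e-05; adjusted p = 0.248 with an estimated correlation), among them PSAE-1 of photosystem I (-0.91 ± 0.10) and ATPC1, the gamma subunit of chloroplast ATP synthase (-0.82 ± 0.10). All 3 measured Calvin cycle genes fell, also adjusted over the list alone: PRK, phosphoribulokinase (-0.81 ± 0.13), SBPASE, sedoheptulose-bisphosphatase (-0.77 ± 0.13), and RCA, RuBisCO activase (-0.48 ± 0.12). That list had a median of -0.77 (adjusted p = 0.00302; adjusted p = 0.248 with an estimated correlation). Calvin cycle calls numbered 1 without wild-type replicate 2 and 2 without any other single array. The call of SBPASE was lost without wild-type replicate 2 (adjusted p = 0.0598), and that of RCA without any one of the 6 arrays (adjusted p = 0.0517 to 0.144). In the chlorophyll and haem list 2 of 7 members fell, and 5 adjusted over the list alone (median -0.30, adjusted p = 0.00536; adjusted p = 0.248 with an estimated correlation). PORB, a protochlorophyllide oxidoreductase, fell by 0.91 ± 0.15, and 1 member fell without wild-type replicate 2, wild-type replicate 3 or msh1 albino replicate 3. Applying quantile normalization again made the differences smaller and ended the calls of LHCB4.1 (-0.27, adjusted p = 0.143), PRK (-0.59, 0.0645), HPR (-0.40, 0.108) and RCA (-0.09, 0.752), as did cyclic loess for PRK (-0.63, 0.0529), HPR (-0.45, 0.0975) and RCA (-0.28, 0.182). Alignment on the spiked controls left the differences as large but ended the calls of LHCB4.1 (-0.72, 0.115), SBPASE (-0.79, 0.0642), HPR (-0.66, 0.192) and RCA (-0.50, 0.485). Quantile normalization also ended the calls of the Calvin cycle list (adjusted p = 0.0664) and the chlorophyll and haem list (0.0536). In the photorespiration list 2 of 3 members fell, also adjusted over the list alone, but the list did not pass (median -0.53, adjusted p = 0.191). Without wild-type replicate 2 or 3 or msh1 albino replicate 2 or 3, 1 member fell; HPR, hydroxypyruvate reductase, had the largest fall (-0.64 ± 0.10).

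Transcripts matched to mitochondrial genes rose as a group: 5 of 16 genes were higher and none lower, and adjusted over the list alone 8 were higher (median 0.35, adjusted p = 4.30e-07; adjusted p = 0.248 with an estimated correlation). The count of higher genes was 1, ccmFN1, without wild-type replicate 1, 2 without wild-type replicate 2, 3 without wild-type replicate 3, 4 without msh1 albino replicate 1 and 5 without msh1 albino replicate 2 or 3. Chromosome 2 carries a copy of mitochondrial DNA, and which copy each probe set reads was not settled here; those of nad5, nad6 and matR share sequence with other transcripts by their names. ccmFN1, for cytochrome c maturation, went from 6.28 ± 0.01 to 6.96 ± 0.03 (mean ± SD, n = 3), and nad5, a subunit of complex I, rose by 1.01 ± 0.20. The call of nad5 was lost without wild-type replicate 1 (adjusted p = 0.0548) or wild-type replicate 2 (0.0795). A second probe set of nad5 gave 0.31 ± 0.26, and 7 probe sets of nad1 gave -0.69 to 0.31, none of them passing; nad1 was named after its values were seen. Alignment on the spiked controls ended the calls of ccmFN1 (adjusted p = 0.185) and, in the mitochondrial stress list, NDB2 (0.127). Among the added groups, 2 of 4 genes for cytochrome c maturation rose (median 0.54, camera adjusted p = 2.34e-04). So did 2 of 10 for respiratory subunits (median 0.32, camera adjusted p = 0.00221). By limma 0 of the respiratory genes passed without wild-type replicate 1 or 2, and 1 passed without wild-type replicate 3 or msh1 albino replicate 1. Of the maturation genes 1 passed without wild-type replicate 1 or 3. Both groups had an adjusted p = 0.339 with an estimated correlation. By fry the adjusted p was 0.0159 for the maturation group and 0.154 for the respiratory group, which lost its call.

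The mitochondrial stress list rose with 3 of 5 members higher, and 5 adjusted over the list alone (median 1.43, adjusted p = 5.63e-05; adjusted p = 0.248 with an estimated correlation). NDB2 (0.73 ± 0.14) and NDB4 (1.43 ± 0.33, from a low wild-type mean of 4.16), alternative NAD(P)H dehydrogenases of mitochondria, rose, as did AT5G09570, a twin-CX9C protein (2.31 ± 0.53). AT2G21640, named after its values were seen, had a difference of 1.79 ± 0.49 (adjusted p = 0.0570). In all 5 genes msh1 albino replicate 3 was the lowest of the albino arrays, as AT5G09570 shows with 7.81, 8.03 and 5.76 in replicates 1 to 3. Without msh1 albino replicate 3 all 5 were called higher. Without wild-type replicate 2 the calls of NDB2 (adjusted p = 0.0558), NDB4 (0.101) and AT5G09570 (0.102) were lost. Those of NDB4 and AT5G09570 were also lost without wild-type replicate 1 (0.0711 and 0.0734), wild-type replicate 3 (0.0940 and 0.0937) or msh1 albino replicate 2 (0.0626 and 0.0581), and that of AT5G09570 without msh1 albino replicate 1 (0.0878).

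Genes of the abscisic acid, cold and drought list fell: 3 of 4 were lower, also adjusted over the list alone (median -0.98, adjusted p = 0.00302; adjusted p = 0.248 with an estimated correlation). LTI30, a dehydrin, fell by 1.72 ± 0.33 and COR15B, a cold-regulated chloroplast protein, by 1.45 ± 0.22. The call of LTI30 was lost without msh1 albino replicate 3 (adjusted p = 0.0538). Without that array 1 of the 4 was lower, and without wild-type replicate 1, wild-type replicate 2 or msh1 albino replicate 1, 2 were, as COR47 lost its call in each of these (adjusted p = 0.0618, 0.0641, 0.0838 and 0.0728). In the senescence list WRKY6 (1.90 ± 0.20) and WRKY53 (1.81 ± 0.41), transcription factors, rose, and SAG29, named after its values were seen, had a difference of -1.06 ± 0.35. Adjusted over the list alone, 2 rose and 1 fell. Over all probe sets without wild-type replicate 2, 1 member was called higher, WRKY6, and 1 was called lower. That list rose with a median of 1.81 and a mean of 0.88 (adjusted p = 0.0480; adjusted p = 0.248 with an estimated correlation). The call was lost in 8 of 19 alternatives (adjusted p up to 0.248 over all of them), among them without wild-type replicate 2 (adjusted p = 0.176) or msh1 albino replicate 3 (0.0722); the call of WRKY53 was also lost without wild-type replicate 1 (0.0638), 2 (0.116) or 3 (0.0739). The sugar starvation list rose as a group although 0 of 3 members passed by limma, with 2 higher adjusted over the list alone (median 0.43, adjusted p = 0.0345; adjusted p = 0.325 with an estimated correlation). MCCA, of leucine breakdown, had 0.55 ± 0.16. That call was lost in 7 of 20 alternatives, among them without wild-type replicate 1 (adjusted p = 0.0675), wild-type replicate 2 (0.0687), msh1 albino replicate 1 (0.0595) or msh1 albino replicate 2 (0.0981).

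The other tested lists did not pass. In the starch list 1 of 4 members fell, and 2 adjusted over the list alone (median -0.24, adjusted p = 0.132), and APL3, a large subunit of ADP-glucose pyrophosphorylase, fell by 0.82 ± 0.09 to a mean of 4.07, a low level whose distance from background was not settled. None of 5 antioxidant genes passed with all arrays, 1 was lower without msh1 albino replicate 1 (TAPX, adjusted p = 0.0494), and 1 was lower adjusted over the list alone (median 0.09, adjusted p = 0.625). None of 4 heat shock genes passed with all arrays, 1 was higher without msh1 albino replicate 3 (AT5G51440, adjusted p = 0.0265), and 2 were higher adjusted over the list alone (median 0.17, adjusted p = 0.170). AT5G51440 is also a member of the mitochondrial stress list. In the anthocyanin and flavonoid list 0 of 4 passed in either way of adjusting (median -0.07, adjusted p = 0.738). Above the 25th percentile of the mean fewer than 3 of its genes were left, so these values do not show that the genes were unchanged. In the reference list 1 of 6 fell, also adjusted over the list alone (median -0.17, adjusted p = 0.236): AT4G33380 fell by 0.34 ± 0.09, a call lost in 15 of 17 alternatives and without any one of the arrays (adjusted p = 0.0758 to 0.140).

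**Figure D3:**
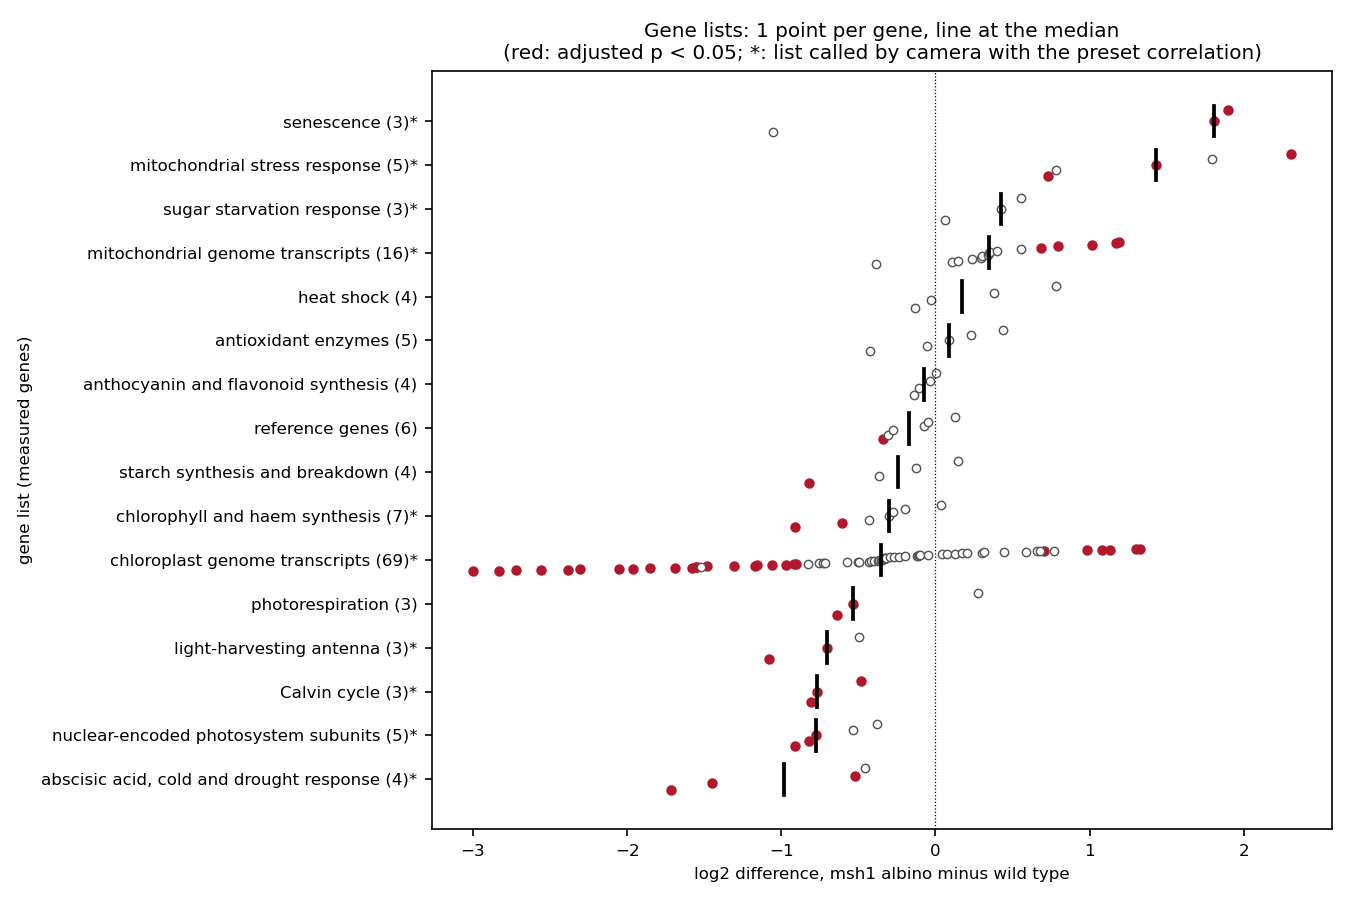
Log2 difference, msh1 albino minus wild type, of each measured gene in the 16 planned lists that were tested, with a line at the median. Red points have an adjusted p under 0.05, and asterisks mark the 10 lists called by camera with the preset correlation.

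Lists with fewer than 3 measured genes were not tested as groups and are given as values. LYC of carotenoid synthesis fell by 0.53 ± 0.09 and OSB1 of organelle genome maintenance by 0.49 ± 0.10; both calls were lost without wild-type replicate 2 (adjusted p = 0.0589 and 0.0660), and that of OSB1 also without wild-type replicate 3 (0.0665) or msh1 albino replicate 3 (0.0538). The defensin PDF1.2 of the jasmonate list rose by 1.00 ± 0.21 and STZ of the high-light list by 2.05 ± 0.51; both calls were lost without wild-type replicate 1 (0.0676 and 0.0584), wild-type replicate 2 (0.0970 and 0.149) or msh1 albino replicate 3 (0.0718 and 0.0679), that of PDF1.2 without msh1 albino replicate 2 (0.0510) and that of STZ without wild-type replicate 3 (0.119). PRL of the cell cycle list fell by 0.53 ± 0.13, a call lost in 10 of 17 alternatives and without any one array except msh1 albino replicate 2 (adjusted p up to 0.147 among these). Genes that did not pass were AT5G15700 of plastid gene expression (0.22), HCT of phenylpropanoid synthesis (-0.23), GRX480 of the salicylate list (0.30), BCAT4 of glucosinolate synthesis (-0.51) and GI of the circadian clock (0.78). Adjusted over the list alone, HCT and BCAT4 were lower, GRX480 and GI higher, and the passing genes of these small lists passed as well. Of markers of other cell types, AT1G22690 of guard cells fell by 1.11 ± 0.19, a call lost without wild-type replicate 2 (adjusted p = 0.0514), while FMA of guard cells (0.00, named after its values were seen), SWEET11 of phloem (-0.05), CLV3 of the shoot meristem (-0.02) and EXPA7 of roots (-0.01) did not pass. CLV3 had a mean below the 25th percentile of all probe sets, so its value does not show that it was unchanged. The nuclear-encoded plastid ribosomal, DNA damage, epidermis and flower lists had 0 genes paired with a single-gene probe set in the annotation used. With 8730 probe sets unnamed, this does not show that the array lacks them.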

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

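Alignment on the hybridization controls and the 16 added lists were chosen after parts of the data had been seen; all other alternatives were planned. No call of a named gene, of a planned or added list or of the WRKY family reversed direction under the alternatives run; for other probe sets only counts were compared. The 98 named genes include genes that did not pass with all arrays. Of the 98, 48 never changed status, 41 lost a call at least once and 9 gained one at least once. The 48 include genes that passed in no alternative, such as CLV3, EXPA7 and SWEET11. The 9 had no call with all arrays, so the 41 losses fall among fewer than 98 called genes. The cause of a change was not tested, except that a stricter threshold reduces counts by construction. Signal near background limits dim probe sets, and counts of 3 to 5 members limit most of the 16 planned lists that were tested. The other 18 planned lists had fewer than 3 measured members and were not tested.

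Counts of higher and lower calls, 854 and 1693 as deposited, were 1301 and 1095 with the 75th percentile aligned and 1717 and 814 with the reference genes aligned. Lower calls were 1047 after cyclic loess and 572 with the hybridization controls aligned. An adjusted p under 0.01 left 251 higher, 438 lower and 195 higher at least 2-fold, and 1 probe set per gene gave 388 and 894, with 177 and 121 at least 2-fold. Above the 50th percentile of the mean, 227 were higher at least 2-fold. Leaving out 1 array gave 298 to 749 higher and 553 to 1424 lower calls, and at least 2-fold 214 to 404 higher and 188 to 281 lower.

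The replicate block, with replicate number as a term, called 564 higher and 921 lower, of which 532 and 891 were also called without it, and it ended the call of the senescence list (median 1.81, adjusted p = 0.143). Arrays with the same number did not share their departures from their group mean (r = 0.01, -0.34 and -0.02 across probe sets), so the numbers were not taken to pair samples.

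The senescence list was not called with the 75th percentile aligned (median 1.89), the reference genes aligned (1.96), cyclic loess (1.87) or quantile normalization again (1.82), and its median ran from 1.29 to 2.12 with 1 array left out. Quantile normalization also ended the calls of the Calvin cycle (-0.59) and chlorophyll and haem (-0.19) lists. The sugar starvation list was not called with the hybridization controls aligned (0.40) or by fry (0.43), and ran from 0.32 to 0.55 with 1 array left out. The starch list was called above the 25th percentile of the mean (-0.36) and by fry (-0.24), and fry called the photorespiration (-0.53) and reference (-0.17) lists. With an estimated correlation no list was called, with medians as before: light harvesting -0.70, photosystems -0.77, Calvin cycle -0.77, chlorophyll and haem -0.30, plastid genome -0.35, mitochondrial genome 0.35, mitochondrial stress 1.43, abscisic acid -0.98, sugar starvation 0.43 and senescence 1.81. Some lists or genes had no value above the 25th or 50th percentile of the mean or without probe sets that share sequence, because their probe sets were removed.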

Other observations

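The tests of uniform plastid RNA loss, of wild-type replicate 1, of the plastid polymerases, of one outlying array and of array scaling, and the comparison of the levels of the neighbours of AT2G07777 with the median probe set, were chosen after the results they concern had been seen. In the nucleus, genes for assembly of photosynthetic complexes and chloroplast biogenesis fell as a group, with 17 of 38 lower and 1 higher (median -0.41, adjusted p = 7.32e-08; adjusted p = 0.339 with an estimated correlation). CaS, the thylakoid calcium sensing protein, fell by 1.47 ± 0.11, and of the nuclear-encoded subunits of the NADH dehydrogenase-like complex NdhN (-1.20 ± 0.18) fell, and NdhL fell by 1.00 ± 0.09. The one higher gene was TAAC (0.56 ± 0.12), named after its values were seen. Lower members numbered 7 without wild-type replicate 2, 10 without wild-type replicate 3, 11 without msh1 albino replicate 3 and 12 to 14 without the others, and TAAC lost its call without wild-type replicate 1 or 2 or msh1 albino replicate 1. Of 43 families tested camera called 1, the WRKY family, with 3 of 6 measured members higher (median 1.12, adjusted p = 0.00106; adjusted p = 0.882 with an estimated correlation and 0.119 by fry). By fry 1 other family was called, SBT (median 0.18, adjusted p = 0.0382), which camera did not call (0.127). WRKY6 and WRKY53 are among the higher WRKY genes and are also the higher members of the senescence list. The calls of the WRKY family and of that list are therefore not independent. WRKY47 rose by 1.13 ± 0.12 and was named after its values were seen.

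The UGT73 to UGT76 glucosyltransferases passed as a group with 2 of 18 higher (median 0.07, mean 0.28, adjusted p = 0.0154; adjusted p = 0.339 with an estimated correlation), and UGT73B4 rose by 2.39 ± 0.26 from a wild-type mean of 4.22, whose distance from background was not settled, and UGT73B5 by 1.70 ± 0.18. That group's call was lost in 5 of 20 alternatives, among them by fry (adjusted p = 0.145) and without wild-type replicate 2 (adjusted p = 0.102) or msh1 albino replicate 1 (0.0594). Of 8 tricarboxylic acid cycle genes 1, SDH1-1, rose, a call lost without any one array except wild-type replicate 3 (adjusted p = 0.0556 to 0.141), and camera called the list higher relative to other genes (median 0.09, adjusted p = 0.0431; adjusted p = 0.339 with an estimated correlation and 0.119 by fry), a call lost in 9 of 20 alternatives, among them without wild-type replicate 3 (0.0891), msh1 albino replicate 1 (0.0812) or msh1 albino replicate 2 (0.0703). Of 11 tau class glutathione transferases 3 rose and 2 fell (median 0.08, adjusted p = 0.214), and GSTU18 fell by 0.98 ± 0.10. Without wild-type replicate 2 or 3, 0 of them were called higher and 1 lower by limma; without wild-type replicate 1, 2 were higher and 1 lower, without msh1 albino replicate 1, 1 and 1, and without msh1 albino replicate 3, 3 and 1. In the iron list BHLH101, a transcription factor of iron deficiency, rose by 1.15 ± 0.16 and 8 others did not pass (median -0.11, mean 0.07, test direction up, adjusted p = 0.693). In the stomatal lineage STOMAGEN, a peptide that promotes stomata, fell by 0.85 ± 0.14 among 4 genes (median 0.01, mean -0.12, test direction up, adjusted p = 0.897). Of 27 expansins and xyloglucan enzymes 1 rose and 2 fell (median 0.03, adjusted p = 0.0762), and the group passed without wild-type replicate 2 (0.0485), where 0 members passed by limma, or msh1 albino replicate 1 (0.0275), where 1 was higher and 1 lower. Without wild-type replicate 3, 0 were higher and 1 lower, and without msh1 albino replicate 2, 1 and 1. None of 9 genes of branched-chain amino acid breakdown passed (median 0.20, adjusted p = 0.0715), although the group passed in 6 of 20 alternatives, among them without wild-type replicate 3 (0.00703) or msh1 albino replicate 3 (0.0302). None of 10 autophagy genes passed (median -0.22, adjusted p = 0.0808), although the group passed in 5 of 20 alternatives, among them without wild-type replicate 2 (0.0485) or msh1 albino replicate 2 (0.00383), where 3 members were lower.

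Of 29 plastid genes for photosynthesis 15 were lower (adjusted p = 0.339 for the group with an estimated correlation), while 6 of 69 plastid genes were higher. A uniform loss of plastid RNA would leave no plastid gene higher, and 6 were; of these rpoC2, rpl36 and ycf3 were also called without each array in turn, and without wild-type replicate 2 or 3 these 3 were the only ones. The difference between the gene groups within an array was 1.37 without wild-type replicate 1 and 1.28 after cyclic loess, which argues against that array and against normalization across the intensity range as the whole source. Less transcription by the plastid-encoded polymerase than by the nuclear-encoded one may contribute, but it cannot be told apart here: of the polymerase, accD and clpP transcripts 2 were called higher and 1, accD, lower. Changes in RNA stability stay open as untested. The state of the albino tissue also stays open and cannot be told apart from the genotype, because the labels name no green msh1 samples.

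AT2G07777 was lower in albino tissue while 5 of 16 mitochondrial genes were higher (adjusted p = 0.248 for the group with an estimated correlation, and 1 gene without wild-type replicate 1). Loss of a stretch of DNA around AT2G07777 would lower its neighbours on chromosome 2, and of the 10 nearest measured loci 0 were called lower by limma and 2 were called higher, AT2G07749 (1.01) and AT2G07678 (0.88), both named after their values were seen. That count decides little: 8 of the 10 lay in the dimmer part of the array, below the median probe set, where 2.74% of probe sets were called lower against 12.1% above it, and the other 2 have probe sets that share sequence with other transcripts. Loss of a stretch, on chromosome 2 or in the mitochondrial genome, may therefore apply and cannot be told apart here. One outlying array is argued against by the highest adjusted p of 0.00392 for AT2G07777 when each array was left out in turn.

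More probe sets were called lower than higher, 1.98 to 1 as deposited. With the arrays aligned on the reference genes the ratio was 0.474, so scaling of the arrays may set which direction leads, and no statement on a general decrease rests on these values. Without msh1 albino replicate 3 the ratio was 1.39, which neither removed the excess nor left it above 1.5 to 1, and the part of that array cannot be told apart. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called as many as 2547 probe sets and the highest of the others called 0 by limma; 10 splits are too few for a share under 0.05.

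Single arrays departed from their group in places. Wild-type replicate 1 had 37 probe sets more than 1.5 lower and 15 more than 1.5 higher on the log2 scale than the mean of the other wild-type arrays. Among the lower ones were 4 plastid genes, such as psaA at 7.79 against 11.18 and 10.86, and ndhH at 5.78 against 8.81 and 8.94, both named after their values were seen. In msh1 albino replicate 2, 72 probe sets were higher and 24 lower by that measure. The 3' minus 5' value of the actin control was 1.64, 1.01 and 1.37 in wild type and 1.34 to 1.46 in albino tissue (exact permutation p = 0.9), and the mean of the hybridization controls was 9.25 in msh1 albino replicate 2 against 8.55 to 8.96 in the other arrays (exact permutation p = 1 between groups).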
